A study of Harpegnathos saltator with 37 samples.

How the data were processed

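Central brains of the ant Harpegnathos saltator were profiled by RNA sequencing in 37 libraries from 7 groups. Per the labels, callow females aged 5 days were moved in sets of 25, with 3 males, into nests without a queen, where some of them duel and become gamergates, workers that mate and reproduce. Dueling was watched, hunting was scored after 100 days, and gamergates at day 120 were recognised by mature oocytes. The central brain was what remained after the optic lobes, the gnathal ganglion and about 95% of the antennal lobes had been removed. Polyadenylated RNA from 600 ng of total RNA was made into strand-specific libraries by dUTP marking, per the labels' protocols.

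The values are FPKM per gene as deposited by the authors in 1 table of 14001 genes. Per the submitters' processing notes the tools were bcl2fastq, STAR and featureCounts. Their versions and the genome build are not given in the sources used here, so no coordinates are printed. A total of 13989 gene identifiers matched a reference table of assembly Hsal_v8.6, which was used for names only, and 12 did not. The reference paired 4117 genes with a symbol and the others with a LOC number. Reads shared between near-identical genes, such as members of the cuticle, odorant binding and cytochrome P450 families, may have been divided or dropped in counting, so values of such members are uncertain.

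Low FPKM values fell on steps of a single read. From these steps whole reads were recovered for 13445 of the 13445 genes above 0, within a tolerance of 0.1 read. The recovered total ranged from 9.2 to 55.78 M reads per library, and the remaining 556 genes were at 0 in every library. Counting error was thus small for genes of moderate level, and the spread between libraries sets the precision. No pair of replicates had values so close that they could be 1 library deposited in duplicate.

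The sequencing run of each library was read from an internal reference in the labels. Duelers and workers at day 10 shared batch 2, both groups at day 20 shared batch 5, and late pupae formed batch 3. At day 120, batch 1 held 1 gamergate and 4 hunting worker libraries, and batch 4 held 5 of each. Caste was therefore compared within a run, or with a run term. Age and developmental stage were fully confounded with the run, so the run and the age or stage cannot be told apart.

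Values were tested as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend. A gene was tested when FPKM was at least 1 in at least 4 libraries, which left 9986 genes. All 37 libraries entered 1 fit with 1 mean per group, a shared estimate of spread, and a run term within day 120. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, two-sided, with 0.05 as the threshold. Fold differences are on the log2(FPKM + 0.5) scale, which understates the change of genes with low values. Means and SDs are of FPKM itself. The labels do not say whether libraries of a group came from separate nests, so p-values measure only the spread between these libraries.

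Caste was compared at days 10, 20 and 120, and the caste differences were compared between days as interactions. Day 120 was compared with day 10 in workers and in gamergates. The later workers were hunting workers and the earlier group of the gamergate comparison were duelers, so age was also confounded with these roles. Late pupae were compared with day 10 workers. The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took up to 8 called genes with a symbol per direction in each caste comparison, 5 in the age and pupa comparisons and 3 in the interactions, ranked by difference, with a mean FPKM of at least 2 in the higher group. It added up to 3 called members of each list in caste comparisons, 2 in the others, and genes fixed by name. Of the genes fixed by name 6 were measured under a symbol, namely Kr-h1, Ecr, usp, Crz, Hr38 and ILP-2. Met, tachykinin and neuroparsin were not found under a symbol and were not analysed here. Vgn was first counted among the fixed genes and taken out after its values had been seen, because the reference does not expand that symbol. It is named only as a called gene. Called genes with a LOC number alone were chosen after their values were seen.

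Fixed lists numbered 26, written as product names and translated to symbols before any value was tested. Of these, 21 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. The calls were repeated with an estimated correlation and with fry. Fry asks whether genes of a list move on balance in 1 direction and does not compare them with other genes. List means between castes were also tested by exact two-sided permutation, over 126 arrangements at days 10 and 20 and 1260 arrangements within runs at day 120.

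Other settings tried were pseudocounts of 0.1 and 1, no filter, FPKM of at least 5, rescaling to TPM, median of ratios scaling, quantile normalization, array weights, a fit on only the groups compared, a replicate block, no run term, batch 4 alone at day 120, other adult groups against the pupae, and leaving out each library. Added after seeing the data were limma-voom on the recovered reads, removal of each library's trend on gene length by lowess with a span of 0.3, a fit without the libraries whose mean squared residual exceeded 2 times the median, and camera without each library in turn. The scaling matters because FPKM do not sum to a constant, and because their denominator was not the sum of recovered reads. The ratio of that sum to the denominator, set to 1 in day 120 gamergate replicate 1, ran from 0.844 to 1.32, highest in day 10 worker replicate 3, so each printed FPKM carries a scaling whose origin is not given in the sources used here. Rescaling to TPM moved the median gene by 0.45 in the worker age comparison, 0.19 in the gamergate age comparison, 0.50 in the pupa comparison and 0.28 in the caste comparison at day 10. Median of ratios scaling moved it by 0.0135 in the pupa comparison and by less in every other, so the deposited values lay near that scale. Ranges of adjusted p over alternatives include the replicate block, although replicate numbers were not taken as a pairing.

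The procedure was tested on simulated data with independent noise, in which 200 of 9986 genes were changed. The changed genes were drawn from those with a mean FPKM above 2, so recovery at lower levels was not measured. Of 2-fold changes, 88% were recovered for caste at day 10, 87% at day 20 and 97% at day 120. For the interactions 67%, 77% and 69% were recovered, for age 90% in workers and 88% in gamergates, and for pupae 80%. Real libraries of a group also share variation, which the simulation left out. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.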

Results

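Expression was measured in the central brain of Harpegnathos saltator, an ant in which workers can become reproductive gamergates after winning dominance duels. The groups were 4 workers and 5 duelers at day 10 after isolation, 4 workers and 5 gamergates at day 20, 9 hunting workers and 6 dominant gamergates at day 120, and 4 late pupae. Depth in M reads was 19.21 to 20.84 in day 10 workers, 19.66 to 24.77 in duelers, 12.73 to 15.1 in day 20 workers and 9.2 to 32.9 in day 20 gamergates. It was 11.09 to 55.78 in hunting workers, 10.46 to 17.29 in day 120 gamergates and 14.49 to 15.91 in pupae.

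The comparison at day 10 asked how the brains of dueling ants differed from those of workers sampled on the same day. CPR1 (LOC105180609), a cuticle list member by its symbol, was 5.85-fold higher in duelers, at 9.08 ± 3.51 FPKM (SD, n = 5) against 1.12 ± 0.516 in workers (n = 4). Its log2 difference was 2.55 (SE 0.41, adjusted p = 0.00282), with 5 of 5 duelers above all workers. LOC105189612, which the reference gives no name, was lower in duelers, at 0.197 ± 0.151 FPKM against 13.4 ± 14.4, with a log2 difference of -3.69 (SE 0.59, adjusted p = 0.00282) and 5 of 5 duelers below all workers. ILP-2 (LOC105188195), an insulin-like peptide gene, stood at 19.8 ± 4.96 FPKM in duelers and 11.3 ± 1.24 in workers, and Crz (LOC105191954), which encodes the neuropeptide corazonin, at 36.9 ± 10.5 and 71.8 ± 39.3. Neither passed over all genes (adjusted p = 0.761 for both), nor did ILP-2 when adjusted over the list alone (0.0912), although all 5 duelers were above all workers for ILP-2. These were the 2 calls among 9986 genes in limma, with 547 genes at unadjusted p under 0.05 where chance gives 499.3, and array weights gave 186 calls. LOC105189612 varied from 2.21 to 33.6 FPKM among workers and was not called without worker replicate 3 (-3.04, adjusted p = 0.0672), under TPM scaling (-4.74, 0.087) or in a fit of only the 2 groups (-3.69, 0.216), over a range of adjusted p from 1.78e-06 to 0.911. The count itself was 4 without worker replicate 2 and 1 without worker replicate 3.

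Of the lists at day 10, ribosomal proteins were lower in duelers by their median, -0.49 (camera adjusted p = 1.71e-19), as were oxidative phosphorylation, -0.25 (6.57e-05), and muscle genes, -0.95 (0.000169). The muscle list varied between single libraries, with a median of -1.72 without dueler replicate 4 and -0.27 without worker replicate 1 (camera adjusted p = 0.439). The oxidative phosphorylation call was lost without dueler replicate 3 (-0.12, 0.146) or worker replicate 4 (-0.09, 0.195), its median was -0.15 without dueler replicate 5, and that of ribosomal proteins was -0.31 without worker replicate 4. None of the 57 ribosomal, 53 oxidative phosphorylation or 13 muscle members passed singly. Under TPM the median of the oxidative phosphorylation list turned to 0.03, but that of all genes was 0.27. All 3 list calls were lost with an estimated correlation (adjusted p = 0.923 for each). By exact permutation the ribosomal list mean gave p = 0.159 (adjusted p = 0.833), oxidative phosphorylation 0.429 (0.848) and muscle 0.270 (0.848). The lowest exact permutation p at day 10 was that of fat body and yolk genes, markers of another tissue, 0.00794 (adjusted p = 0.167), with 5 of 5 duelers below all workers. That list had a mean of -0.36 and a median of -0.13 and did not pass camera (adjusted p = 0.479).

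At day 20, gamergates were compared with workers, and ILP-2 was the called gene. It was 4.97-fold higher in gamergates, at 45.0 ± 18.7 FPKM (SD, n = 5) against 7.99 ± 1.31 in workers (n = 4), with a log2 difference of 2.31 (SE 0.29, adjusted p = 4.81e-05) and 5 of 5 gamergates above all workers. Crz stood at 29.0 ± 12.1 FPKM in gamergates and 71.5 ± 23.4 in workers, a log2 difference of -1.34 (SE 0.47) with 5 of 5 gamergates below all workers. It passed when adjusted over the list alone (0.0211) and not over all genes (adjusted p = 1). Kr-h1 (LOC112589664), a transcription factor gene induced by juvenile hormone, was low in both castes, at 0.839 ± 1.43 and 0.352 ± 0.331 FPKM. In limma 1 gene of 9986 was called and 215 had an unadjusted p under 0.05 against 499.3 by chance. ILP-2 lost its call in a fit of only the 2 groups (2.31, adjusted p = 0.0601; range over alternatives 6.37e-07 to 0.332). The count was 2 without gamergate replicate 2 or 3 or worker replicate 3 or 4, and 3 without gamergate replicate 4 or worker replicate 2. No list passed camera, where the lowest adjusted p was 0.226, and of 14 neuropeptide genes 1 was higher, which was ILP-2.

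At day 120, dominant gamergates were compared with hunting workers. ILP-2 was 2.98-fold higher in gamergates, at 18.3 ± 6.39 FPKM (SD, n = 6) against 5.85 ± 1.97 (n = 9), and the gene with the symbol Vgn (LOC105181726) was 30.3-fold higher, at 1326 ± 1339.8 against 61.9 ± 111. Crz was 5.01-fold lower in gamergates, at 20.9 ± 10.2 FPKM against 126 ± 82.5, and Kr-h1 was 3.92-fold lower, at 0.680 ± 0.523 against 5.39 ± 3.71. In log2 units the differences were 1.58 for ILP-2 (SE 0.24, adjusted p = 0.00214, 6 of 6 gamergates above all workers) and 4.92 for Vgn (SE 0.92, 0.0175, 3 of 6 above). They were -2.32 for Crz (SE 0.38, 0.00281, 6 of 6 below all workers) and -1.97 for Kr-h1 (SE 0.40, 0.04, 5 of 6 below). The unnamed LOC105189251 was lower in 6 of 6 gamergates, at 1.35 ± 0.383 against 5.80 ± 2.70 FPKM (-1.55, adjusted p = 0.00281), and so was LOC105184868, at 30.5 ± 2.54 against 51.1 ± 9.64 (-0.72, adjusted p = 0.0439).

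Between the castes at day 120, limma called 6 of 9986 genes, 2 higher and 4 lower in gamergates, and limma-voom on recovered reads called 3. In limma 1440 genes had an unadjusted p under 0.05, where chance gives 499.3. With array weights 187 genes were called, and without the run term 47. Within batch 4 (5 against 5) and batch 1 (1 against 4), the differences were 1.54 and 1.70 for ILP-2, 4.87 and 5.08 for Vgn, -2.27 and -2.48 for Crz, and -2.18 and -1.34 for Kr-h1. They were -1.42 and -1.93 for LOC105189251 and -0.66 and -0.92 for LOC105184868. No gene was called without gamergate replicate 1, the only gamergate of batch 1, or in batch 4 alone, or in a fit of only the 2 groups. Without that library the differences kept between 0.909 and 1.10 times their size, and the adjusted p rose to 0.053 for ILP-2, 0.0798 for Crz, Kr-h1 and LOC105189251, 0.132 for Vgn and 0.485 for LOC105184868. Over all alternatives the adjusted p ranged from 2.71e-05 to 0.988 for ILP-2, 7.5e-05 to 0.988 for Crz, 0.000463 to 0.998 for Kr-h1 and 0.00169 to 0.997 for Vgn, and reached 0.988 for LOC105189251 and LOC105184868. These ranges include the replicate block, although replicate numbers were not taken as a pairing of libraries. Kr-h1 also lost its call under TPM scaling (-2.50, adjusted p = 0.164), by voom (-2.55, 0.235), in 10 of the fits leaving out 1 library, with a pseudocount of 0.1 (adjusted p = 0.124), with no filter (0.056) and with FPKM of at least 5 (0.0845). LOC105184868 was the least stable, lost with a pseudocount of 0.1 (adjusted p = 0.0935), no filter (0.056), TPM (0.146), voom (0.123), without the libraries standing apart (0.109) and in 11 of the fits leaving out 1 library. Vgn lost its call by voom (5.21, 0.141), without gamergate replicate 2 (0.0662), 5 (0.0518) or 6 (0.0647) and without hunting worker replicate 6 (0.0556) or 7 (0.0742). The count was 3 without gamergate replicate 2 or 6 or hunting worker replicate 7, 11 without hunting worker replicate 4 and 13 without hunting worker replicate 5.

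**Figure D1:**
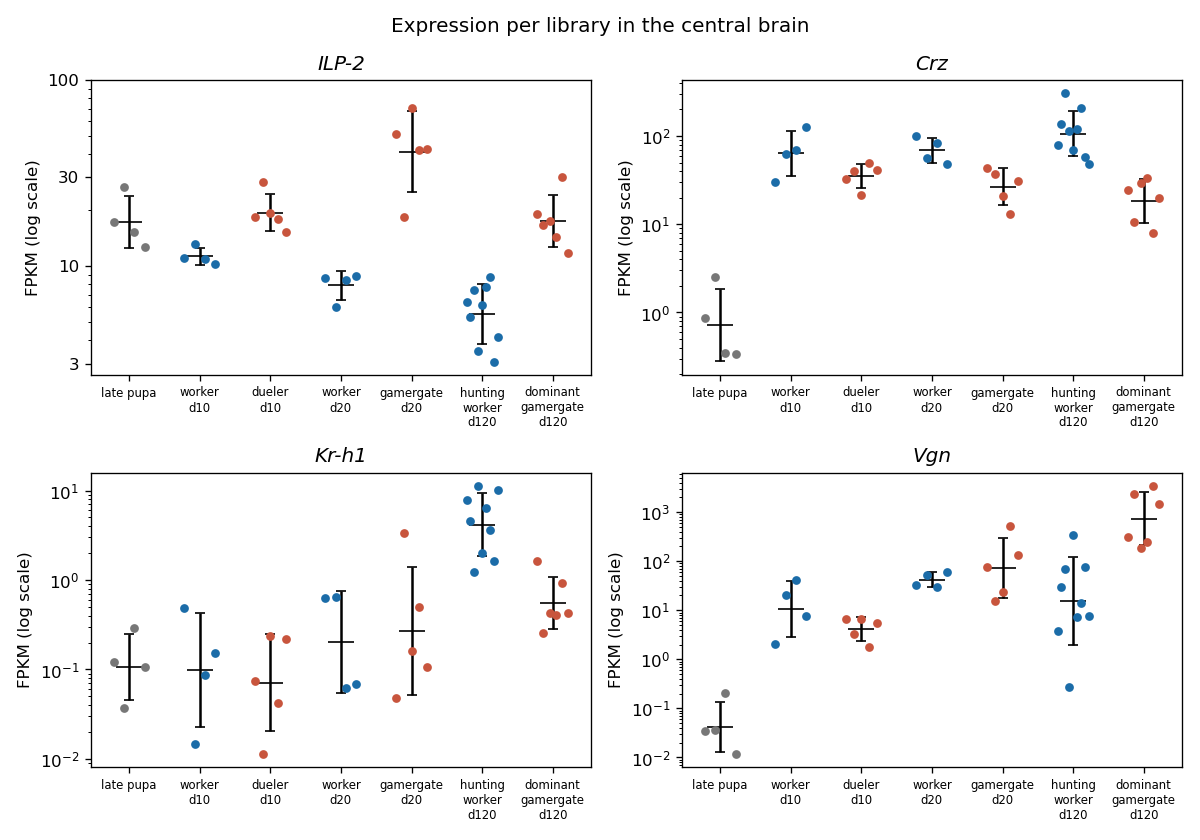
FPKM of ILP-2, Crz, Kr-h1 and Vgn in each library (points) of the 7 groups, on log axes, with a dash and bars for the mean ± 1 SD on the log2 scale. At day 120 the 6 gamergates lay above all 9 hunting workers for ILP-2 and below all of them for Crz.

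Of the lists at day 120, oxidative phosphorylation was lower in gamergates by a median of -0.34 (camera adjusted p = 1.49e-14) and ribosomal proteins by -0.22 (6.90e-05). Neural development genes were higher by 0.16 (0.00133) and chromatin genes by 0.13 (0.0117), calls that ended when the trend on gene length was removed (adjusted p = 0.306 and 0.230). No member of these 4 lists passed singly, and all calls were lost with an estimated correlation (adjusted p = 0.776 for ribosomal proteins and 0.631 for the others). Of 14 neuropeptide genes, ILP-2 was higher, Crz lower and 12 were not called, with camera adjusted p = 0.0587 and an exact permutation p of 0.00238 (adjusted p = 0.05). By exact permutation within runs the list means gave p = 0.0333 for oxidative phosphorylation (adjusted p = 0.143), 0.321 for ribosomal proteins (0.481), 0.0198 for neural development (0.139) and 0.0341 for chromatin (0.143). For ribosomal proteins 0 of 6 gamergates lay below all workers, and the camera call was lost without hunting worker replicate 7 (-0.07, adjusted p = 0.0782). Genes of the retina and optic lobe, tissue removed at dissection, had a median of -0.59 that did not pass (camera adjusted p = 0.144, exact permutation p = 0.247). Fat body and yolk genes, markers of another tissue, had a median of 0.18 and a mean of 0.42 and did not pass either (camera adjusted p = 0.0587, exact permutation p = 0.0619). None of its 9 members passed over all genes and 2 were higher when adjusted over the list alone. Vgn, called at this day, is not among these members. Within batch 4 and batch 1 the differences were 3.33 and 0.01 for Hex70a and 0.74 and 0.49 for apolpp.

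The interactions asked whether the caste difference changed between days. In limma none of 9986 genes passed between day 20 and day 10, between day 120 and day 10 or between day 120 and day 20, and voom called 0 in each. The genes at unadjusted p under 0.05 in limma numbered 300, 320 and 646, where chance gives 499.3. With array weights the counts were 1, 106 and 0. Adjusted over the list alone, the ILP-2 difference was larger at day 20 than at day 10 by 1.56 (SE 0.42, adjusted p = 0.00404, over all genes 0.895). For Kr-h1 the difference at day 120 was below that at day 10 by a log2 value of -1.85 (SE 0.62, 0.034, over all genes 1) and below that at day 20 by -2.24 (SE 0.62, 0.00635, over all genes 0.663). At days 10 and 20 the mean of Kr-h1 was under 1 FPKM in both castes, so a caste difference could hardly show there. For Crz the change from day 10 to day 120 was -1.49 (SE 0.60) and did not pass over the list alone (0.0571). Crz and ILP-2 thus differed by caste past the threshold at some days and not at others. In the main fit neither had a difference between days that passed over all genes. Across genes, which are not independent replicates, caste differences at day 10 and day 120 had a Pearson correlation of 0.256 and Spearman 0.431, and 29 and 25 of 100 labellings of caste, counting the real one, gave as much. Correlations were 0.0222 and -0.112 for day 10 with day 20, where 89 and 68 labellings gave as much, and -0.0725 and -0.187 for day 20 with day 120 (64 and 44). ILP-2 was the 1 gene called at both day 20 and day 120.

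Workers at day 120, all of them hunting workers, were compared with workers at day 10, who were not selected for hunting. Age, sequencing run and selection for hunting cannot be told apart in this comparison. Kr-h1 was 7.38-fold higher in old workers, at 5.39 ± 3.71 FPKM (SD, n = 9) against 0.186 ± 0.210 (n = 4), with a log2 difference of 2.88 (SE 0.43, adjusted p = 1.23e-05). Bcat rose by 1.62 (66.5 ± 35.6 against 19.9 ± 6.42 FPKM, adjusted p = 0.00137, 8 of 9 libraries above all young ones), and Cds by 1.32 (0.000114), Miox, myo-inositol oxygenase, by 1.46 (0.00175) and the mitochondrial ribosomal protein gene mRpL46 by 1.32 (9.08e-05), each in 9 of 9. Among called genes with a symbol, the steepest fall was in apd-3l (LOC105189609), from 10583 ± 11398 to 0.210 ± 0.217 FPKM (-12.34, SE 1.57, adjusted p = 8.44e-07, 9 of 9 below). The cuticular protein gene Cpr97Ea fell from 88.7 ± 102 to 0.0388 ± 0.0391 FPKM (-5.99, adjusted p = 4.44e-05), and Cpap3-d (-4.11), conv (-3.21) and Scp1 (-3.46) fell as well. Scp1 was not called without day 10 worker replicate 1 (-2.24, adjusted p = 0.0771, range over alternatives 0.00154 to 0.130). ILP-2 fell from 11.3 ± 1.24 to 5.85 ± 1.97 FPKM (-0.96, SE 0.26, adjusted p = 0.00809, 9 of 9 below), a call lost under TPM (-0.56, adjusted p = 0.0724). Crz, at 126 ± 82.5 against 71.8 ± 39.3 FPKM, did not pass (0.77, adjusted p = 0.18), but did under TPM (1.24, 0.0142) and quantile normalization (1.02, 0.0471). Under TPM the median of all genes in this comparison was 0.46.

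In workers 2460 of 9986 genes were called by age, 1299 higher and 1161 lower, of which 318 changed over 2-fold, and 4874 with array weights. The split was 5529 higher and 259 lower under TPM, where the median gene moved by 0.45, and 1252 against 901 with quantile normalization. Without day 10 worker replicate 3 the count was 1290.

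Energy metabolism and several nervous system lists passed camera as lower in old workers at the preset correlation. With an estimated correlation no list call held (adjusted p = 0.476 for cuticle and chemosensory genes and 0.75 for the others called), and TPM turned the medians of 6 lists. Of 53 oxidative phosphorylation genes 19 fell and 1 rose (median -0.42, camera adjusted p = 4.46e-05), among them ATPsyngamma, from 159 ± 25.5 to 91.9 ± 23.3 FPKM. Ribosomal proteins had a median of -0.31 (0.000771) with 4 of 57 lower. Of 22 neural development genes 10 fell (-0.36, 0.00433), such as the axon guidance gene Sema1a, from 102 ± 13.2 to 59.2 ± 9.97 FPKM, and the adhesion gene Nrg. Of 11 mushroom body genes 4 fell (-0.42, 0.00992) and of 16 neuronal genes 3 (-0.25, 0.0311), with the synaptic gene cpx at 164 ± 48.8 against 304 ± 52.4 FPKM. Under TPM the medians became 0.03 for oxidative phosphorylation, 0.15 for ribosomal proteins, 0.08 for neural development, 0.04 for mushroom body, 0.21 for neurons and 0.15 for chemosensory genes. The median of all genes under that scaling was 0.46, above each of these list medians. The call of the neurons list ended when the trend on gene length was removed (adjusted p = 0.142), and without day 10 worker replicate 1 (0.0748) or 4 (0.05) or hunting worker replicate 3 (0.0885) or 7 (0.0558). Without day 10 worker replicate 4 the median was -0.15 for ribosomal proteins (0.0745) and -0.28 for oxidative phosphorylation (0.0129), and without replicate 1 it was -0.52 for ribosomal proteins. TPM also ended the calls of Sema1a (-0.33, adjusted p = 0.0535), Nrg (-0.33, 0.0545) and cpx (-0.45, 0.0887), and cpx was not called without day 10 worker replicate 3 (-0.83, 0.0595).

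Lists of other tissues moved too. Of 13 muscle genes 6 fell (median -1.12, camera adjusted p = 0.00305; -0.44, 0.0636 without day 10 worker replicate 1), including the troponin genes wupA (-2.18) and TpnT (-1.26). The first was not called without day 10 worker replicate 1 (-1.52, adjusted p = 0.0965) or replicate 3 (-1.97, 0.0686), and the second was -0.64 without replicate 3. Of 12 cuticle genes 7 fell and 1 rose (-1.11, 0.00433), with CPR5 at -1.16, or -0.71 without day 10 worker replicate 1. The median of the cuticle list was -0.69 without day 10 worker replicate 3 (0.0215). Chemosensory genes had 4 of 10 lower and 1 higher (-0.28, 0.0281; 0.05 without day 10 worker replicate 4). Of these the odorant binding protein gene Obp10 fell from 1169 ± 344 to 390.5 ± 170.2 FPKM (-1.62, adjusted p = 1.58e-05, 9 of 9 below). Cell cycle genes were higher (0.24, 0.00988), with 4 of 22 called, among them CycB3 (0.47), which was not called without day 10 worker replicate 3 (0.43, adjusted p = 0.0525).

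Among lists that did not pass camera in workers, 4 of 13 glial genes fell. The glial receptor gene moody went from 30.9 ± 4.36 to 13.6 ± 2.63 FPKM (-1.16, adjusted p = 0.000363, 9 of 9 below) and the GABA transporter gene Gat-1B from 149 ± 31.5 to 79.6 ± 8.84 (-0.88, 4.44e-05). Of 16 biogenic amine genes 3 fell, with the vesicular monoamine transporter gene Vmat lower in 8 of 9 libraries than in any young one (-0.97, adjusted p = 0.000638). Of 34 chromatin genes 5 rose and 2 fell, with CoRest at 0.42, and of 10 immune genes 2 rose and 1 fell, with Rel, the NF-kappa-B gene of the immune response, at 13.3 ± 0.816 against 9.48 ± 0.761 FPKM. Neuropeptide genes had 1 higher and 2 lower of 14, their receptors 0 higher and 3 lower of 9, insulin and TOR genes 1 higher and 1 lower of 14, heat shock genes 1 higher of 8 and fat body genes 1 lower of 9. No member of the clock, ecdysone or retina list was called in limma. For fat body genes the median was 0.03 and the mean -0.26, and the immune and insulin lists had negative medians (-0.01 and -0.07) with an upward test.

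Gamergates at day 120 were compared with duelers at day 10, again across sequencing runs. Vgn was 105-fold higher in gamergates, at 1326 ± 1339.8 FPKM (SD, n = 6) against 4.73 ± 2.15 (n = 5), with a log2 difference of 6.71 (SE 1.06, adjusted p = 3.62e-05, 6 of 6 above all duelers). Bcat rose from 24.4 ± 10.7 to 61.3 ± 15.7 FPKM (1.52, adjusted p = 0.00438), DNaseII by 1.37 (9.78e-05) and cue by 1.20 (2.61e-05), each in 6 of 6. Hex70a, a hexamerin storage protein gene, stood at 15.1 ± 17.7 against 0.0634 ± 0.0832 FPKM (2.82, adjusted p = 0.00592, 4 of 6 above), a call lost by voom (4.33, 0.393) and in a fit of only the 2 groups (2.02, 0.182). The gene apd-3l fell from 5127 ± 4769.9 to 0.154 ± 0.240 FPKM (-10.35, adjusted p = 4.04e-05), Cpr97Ea by a log2 value of -4.73 (0.00129), and CPR1, the gene higher in duelers than in workers, from 9.08 ± 3.51 to 1.44 ± 0.572 FPKM (-2.24, 0.0001), each in 6 of 6. Mp20 fell too (-2.50, adjusted p = 0.00371, 6 of 6), as did Cpap3-d (-3.12, 0.0129, 2 of 6), which was not called without dueler replicate 4 (-2.55, 0.0543), and Cpr97Ea was not called by voom (-7.19, 0.175). Kr-h1 did not pass, at 0.680 ± 0.523 against 0.116 ± 0.104 FPKM (1.03, adjusted p = 0.0913). It did pass under other settings, with a pseudocount of 0.1 (1.99, adjusted p = 0.0317), TPM (2.17, 0.0244), only the groups compared (1.24, 0.00307), array weights (1.28, 0.00242) and without the libraries standing apart (1.17, 0.0326).

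In gamergates 2510 genes were called by age, 1312 higher and 1198 lower, 296 of them over 2-fold, 6138 with array weights, and 1996 higher against 459 lower under TPM. Without gamergate replicate 1 the count was 1503. Of 53 oxidative phosphorylation genes 26 fell and none rose (median -0.50, camera adjusted p = 3.64e-09, with an estimated correlation adjusted p = 0.744), for example ATPsynbeta, from 199.6 ± 15.5 to 111 ± 11.3 FPKM (-0.81, 4.42e-05, 6 of 6). Of 22 cell cycle genes 11 rose and none fell (0.34, 0.00101), such as the replication gene Mcm6 (0.56) and CycA (0.50). Of 34 chromatin genes 7 rose and 1 fell (0.23, 0.0177), with the histone demethylase gene Utx at 17.6 ± 2.42 against 8.47 ± 1.54 FPKM (0.93, 0.00245) and CoRest at 0.46. Of 14 neuropeptide genes 3 fell (-0.43, 0.0245), and Eth, which encodes ecdysis triggering hormone, went from 4.09 ± 2.15 to 0.413 ± 0.289 FPKM (-2.13, 2.14e-05, 6 of 6), while the gene of its receptor, ETHR, fell by 0.59. The last 3 list calls were lost with an estimated correlation (adjusted p = 0.562 for each), and no list median that passed turned under TPM.

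Outside these lists in gamergates, Obp10 fell from 794.8 ± 221 to 289.6 ± 25.2 FPKM (-1.32, adjusted p = 0.000463), moody by 1.03, Gat-1B by 0.84 and Vmat by 0.84, each in 6 of 6. ImpL2, which encodes a binder of insulin-like peptides, fell by 1.08 (adjusted p = 0.00995, 6 of 6). Rel rose by 0.54, Dscam3 by 0.90 and VGlut, the vesicular glutamate transporter gene, by 0.68, each in 6 of 6. Glial genes had 1 higher and 4 lower of 13, with a median of 0.17 and a mean of -0.22. Members called were 1 higher and 5 lower of 10 for chemosensory genes (camera adjusted p = 0.0609), 1 higher and 5 lower of 12 for cuticle (0.0624), and 2 higher of 13 for ecdysone genes. They were 2 higher of 9 for fat body, 2 higher and 1 lower of 14 for insulin and TOR, 2 higher and 1 lower of 22 for neural development, and 1 higher and 2 lower of 16 for neurons. The other lists had at most 2 called members, and no member of the muscle, ribosomal protein or clock list was called in limma. The called gene Mp20 is not on the muscle list.

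Both age comparisons called 1590 genes in the same direction, 819 higher and 771 lower, and 0 in opposite directions, where independent lists would share 170.7 higher and 139.3 lower. They share no library but share the sequencing runs, so part of the overlap may come from the runs. In the main fit the age effect was not shown to differ between castes for any gene over all genes, as given by the interaction of day 120 with day 10. With array weights that interaction called 106 genes.

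Late pupae were compared with day 10 workers, where stage and run cannot be told apart. Hr4, a nuclear receptor gene of the ecdysone response, was 33.5-fold higher in pupae (n = 4) than in workers (n = 4), where it stood at 1.28 ± 0.322 FPKM (SD), with a log2 difference of 5.07 (SE 0.20, adjusted p = 8.45e-20). The ecdysone-induced transporter gene E23 (84.2 ± 44.5 against 2.68 ± 0.369 FPKM, 4.51), Cpap3-b (4.03), the cadherin gene stan (3.99) and Apoltp (3.69) were higher in 4 of 4 pupae. Crz was at 1.01 ± 1.02 against 71.8 ± 39.3 FPKM (-5.62, SE 0.49, adjusted p = 3.27e-11), Tpx-4 at a log2 difference of -5.36 (9.11e-17) and spab at 52.4 ± 63.8 against 1107 ± 283 (-4.98, 6.38e-13), each lower in 4 of 4. The gene apd-3l was lower by a log2 value of -10.65 (1.24e-05), or -5.15 against day 20 workers, and Cpr97Ea by -5.22 (0.00031), which turned to 0.02 against day 20 workers and was not called by voom (-8.03, 0.0743). Of other fixed genes, usp, the ecdysone receptor partner, was at 7.80 ± 3.27 against 31.1 ± 2.57 FPKM (adjusted p = 2.67e-10) and Hr38 at -2.31, while ILP-2 (0.59, 0.103) and Kr-h1 (-0.07, 0.911) did not pass. ILP-2 did pass under TPM (1.11, adjusted p = 0.00284), against day 20 workers (1.08, 0.00339) and in a fit of only the groups compared (0.0412). Ecr was lower by a log2 value of -0.42 (adjusted p = 0.0331). Under TPM it was 0.05, where the median of all genes was 0.51. Ecr was not called without late pupa replicate 1 (0.109), 3 (0.0539) or 4 (0.0733) or without day 10 worker replicate 2 (0.0501), 3 (0.0752) or 4 (0.124). In all 5726 genes were called, 3054 higher and 2672 lower, 1842 of them over 2-fold, and 5240 against 1170 under TPM.

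Of 22 neural development genes 18 were higher in pupae and none lower (median 1.08, camera adjusted p = 9.77e-06). No list call in pupae held with an estimated correlation, where the adjusted p was 0.366 for neuropeptides, 0.572 for neurons and ribosomal proteins and 0.565 for the others called. Those higher included Fas3, at 22.7 ± 4.74 against 5.13 ± 0.409 FPKM, and the midline guidance gene sli, at 23.5 ± 2.57 against 7.27 ± 0.254. Of 22 cell cycle genes 14 rose and 1 fell (0.57, 0.0129), among them Top2 (1.00) and dpa (1.31). Late pupa replicate 2, the library farthest from its group, did not show that rise, with a mean log2 level of the list of 1.92 within the 1.89 to 1.96 of the workers, where the other pupae had 2.53 to 2.76. Neuropeptide genes fell, 11 of 14 (-1.69, 0.000132), with Dh31 at 34.3 ± 21.5 against 163 ± 13.5 FPKM. Of 16 neuronal genes 8 fell and 2 rose (-0.42, 0.0496), although late pupa replicate 2 lay above all workers by its list mean. Under TPM the median of the neurons list was 0.08 and that of all genes 0.51. The synaptic gene cpx was at 62.9 ± 43.6 against 304 ± 52.4 FPKM, and of 11 mushroom body genes 8 fell and 1 rose (-0.74, 0.0293). Of 53 oxidative phosphorylation genes 42 fell and 1 rose (-0.78, 3.25e-06), and of 57 ribosomal protein genes 27 fell (-0.67, 0.000143). Muscle genes fell in 10 of 13 and rose in 1 (-2.46, 0.0199), and retina genes fell in 5 of 9 (-2.48, 0.0435), with the arrestin gene Arr2 at 9.37 ± 7.09 against 550.3 ± 368.6 FPKM. The neurons call was also lost without late pupa replicate 1 (-0.28, 0.112), 3 (0.0691) or 4 (0.0624) or day 10 worker replicate 1 (0.0759) or 3 (0.058), and its median was -0.74 without late pupa replicate 2. The retina call was lost without late pupa replicate 1 (0.055) or 2 (0.053) or day 10 worker replicate 1 (0.0805), 2 (0.0525) or 3 (0.0713). The mushroom body call was lost without late pupa replicate 1 (0.0535) or day 10 worker replicate 1 (0.061), and the muscle call without the latter (0.0735).

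The level of apd-3l differed widely within groups at days 10 and 20. It was 6731, 9347 and 9475 FPKM in 3 duelers and at most 66.2 in the other 2, and 7267, 8151, 26806 and 111 in the day 10 workers. It was 6.85, 2953, 72.7, 1573 and 1439 FPKM in the day 20 gamergates and 47.8, 98.1, 8.79 and 949 in the day 20 workers. Comparisons of cuticle genes that include a group of day 10 or day 20 therefore rest on libraries that were far from uniform.

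**Figure D2:**
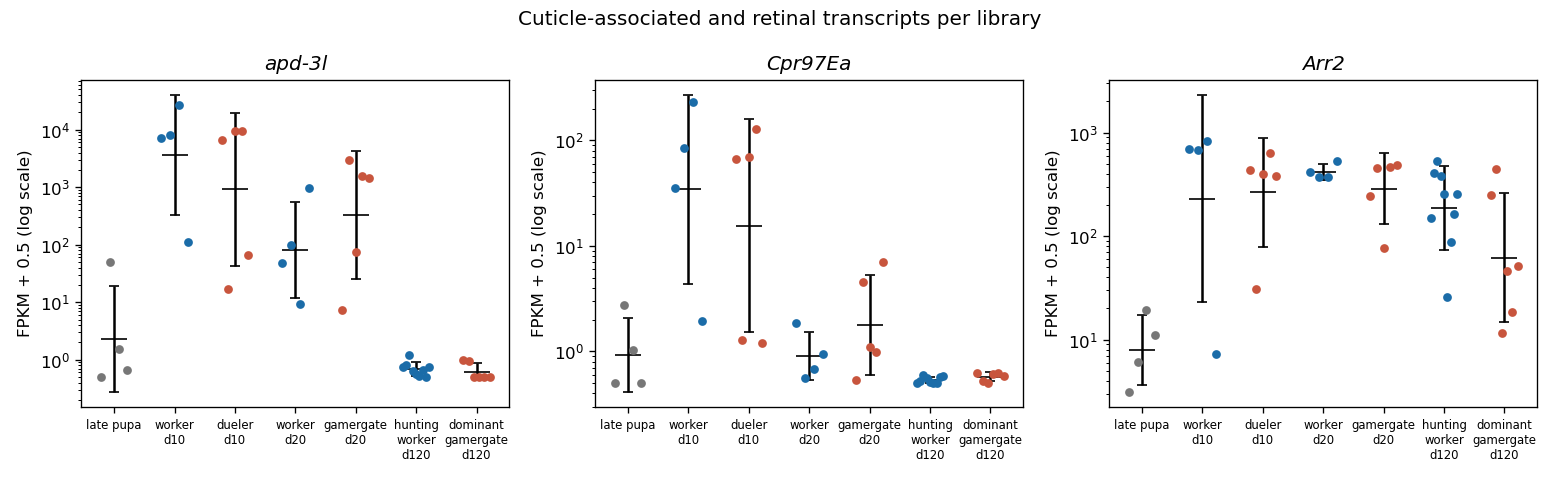
FPKM + 0.5 of apd-3l, Cpr97Ea and Arr2 in each library (points) of the 7 groups, on log axes. In day 10 workers apd-3l ran from 111 to 26806 FPKM, and at day 120 it was at most 0.721 FPKM.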

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

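The interactions and the gene fits leaving out each library were planned. The fit without the libraries standing apart and camera without each library in turn were added after the data were seen. Over all pairs of a named gene and a group, 23 held a library apart from the rest by the gap rule, where 15.7 would be expected by chance.

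Late pupa replicate 2 accounted for 8 of these. It had spab at 148 FPKM against 18.6 to 23.7 in the other pupae, per at 7.64 against 1.30 to 1.49, Ir25a at 4.56 against 1.10 to 1.33, Mf at 1.00 against 0.0758 to 0.171 and yellow-b at 28.8 against 6.90 to 8.19. Gli was at 7.23 FPKM against 11.3 to 12.0, Sirt7 at 13.5 against 23.1 to 25.4 and Hsc70-5 at 42.8 against 47.1 to 47.7. Its mean squared residual over all genes was 3.09 times the median library. Pgrp-s2 was at 0 in late pupa replicate 1 against 0.0307 to 0.0320 FPKM, which is too low to be told from not detectable.

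Day 10 worker replicate 4 had the retinal gene Arr2 at 6.74 FPKM against 675 to 826 in the other 3 workers, the opsin gene Uvop at 1.31 against 11.2 to 14.4, and Eth at 1.45 against 3.05 to 3.26. Day 10 worker replicate 3 had the troponin gene TpnT at 22.7 FPKM against 3.26 to 3.98 and Hr4 at 1.76 against 1.09 to 1.14. Thor was at 93.9 FPKM in day 10 worker replicate 1 against 129 to 138. Among duelers, Uvop was at 1.36 FPKM in replicate 2 against 7.13 to 10.7, and Hex70a at 0.209 in replicate 4 against 0 to 0.0521.

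ILP-2 was at 6.05 FPKM in day 20 worker replicate 2 against 8.43 to 8.90. Among hunting workers, Miox was at 10.9 FPKM in replicate 4 against 0.511 to 2.09, ETHR at 4.01 in replicate 7 against 2.14 to 2.82, and Scp1 at 0.968 in replicate 2 against 0 to 0.268. Among day 120 gamergates, Hr38 was at 3.11 FPKM in replicate 1 against 5.79 to 7.07, and Cyp301a1 at 0.0287 in replicate 3 against 0 in the others, a level too low to be told from not detectable.

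Adjusted over the list alone, the caste difference changed between days for ILP-2, by 1.56 from day 10 to day 20, and for Kr-h1, by -1.85 from day 10 to day 120 and -2.24 from day 20 to day 120.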

How the results depend on the processing

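With array weights 186 genes were called for caste at day 10, 4 at day 20 and 187 at day 120. With them the interactions gave 1 gene between days 10 and 20 and 106 between days 10 and 120, and the age comparisons 4874 in workers and 6138 in gamergates. The cause was not tested. TPM rescaling gave 1 gene for caste at day 10, 1 for the interaction of days 10 and 120 and 5788 for age in workers, because the FPKM sums of the libraries differ. With FPKM of at least 5, 1 gene was called at day 10, and with a pseudocount of 1, 3 genes at day 20. Fits of only the groups compared gave 2 genes at day 20, 0 at day 120 and 1 for the interaction of days 10 and 120.

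For caste at day 120, 47 genes were called without the run term, 14 with quantile normalization, 3 by voom and 0 in batch 4 alone. Leaving out 1 library gave 1 to 4 genes for caste at day 10, 1 to 3 at day 20 and 0 to 13 at day 120. The interactions ranged from 0 to 1 for days 10 and 20, 0 to 2 for days 10 and 120, and 0 to 3 for days 20 and 120. The age counts ranged from 1290 to 3012 in workers and 1503 to 2836 in gamergates, and the pupa count from 5186 to 5879.

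A replicate block in a fit of only the groups compared gave 0 genes for caste at days 10, 20 and 120, 86 for age in workers and 803 in gamergates. Without the block those fits gave 3, 2, 0, 1902 and 2833. Replicate numbers were not taken as a pairing, since correlations of libraries with the same number ran from -0.128 to 0.450, not all over 0.1, and 3 of 14 matched best with their own number. At day 20 all 4 were positive, from 0.0993 to 0.450, and 2 matched best with their own number, so a shared origin there is not excluded.

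With an estimated correlation 0 lists were called for caste at day 10 and day 120, age in workers, age in gamergates and pupae. Fry called 0 lists for caste at day 10 and 0 at day 120, 4 for age in workers and 18 for pupae. Removing the length trend left 2 lists for caste at day 120, oxidative phosphorylation and ribosomal proteins. Directions turned for Ecr under TPM, to 0.38 with age in workers and 0.053 in pupae. The medians of all genes under that scaling were 0.46 and 0.51, so Ecr stayed below them in both comparisons. In pupae against day 20 workers, directions turned for Cpr97Ea, to 0.0236, and Cyp301a1, to 0.34.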

Other observations

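Among the tests of explanations in this section, those of the length trend and of the relation of apd-3l to tissue lists were chosen after the result was seen. The other tests of explanations were planned. In late pupae, lists that did not pass camera still held many called members. Of 34 chromatin genes 18 were higher and 7 lower (adjusted p = 0.0715), of 13 glial genes 7 and 3 (0.245), of 14 insulin and TOR genes 7 and 3 (0.327), and of 8 heat shock genes 6 and 0 (0.0602). Of 9 neuropeptide receptor genes 5 were higher and none lower (0.0599), among them rk, the receptor gene of the cuticle tanning hormone bursicon, at 17.5 ± 1.73 against 3.75 ± 1.16 FPKM (SD, n = 4 each, log2 difference 2.12, adjusted p = 2.57e-10). Of 16 biogenic amine genes 3 were higher and 7 lower (0.116). The serotonin receptor gene 5-HT2A stood at 31.2 ± 4.69 against 9.25 ± 1.60 FPKM, and Hdc, needed for histamine synthesis, at 1.58 ± 1.01 against 23.4 ± 8.42 (-3.55, 3.88e-12, 4 of 4 below). Cuticle genes had 2 higher and 8 lower of 12 (0.0565), ecdysone genes 4 and 4 of 13, fat body genes 4 and 1 of 9, clock genes 2 and 2 of 5, chemosensory genes 2 and 3 of 10 and immune genes 1 and 2 of 10.

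Lists with fewer than 5 tested members were only counted. The cytochrome P450 list had 2 of 4 lower with age in both castes and in pupae, and Cyp4aa1 fell with age in workers (-1.73, adjusted p = 6.98e-09). Exocrine gland genes had 1 higher and 2 lower of 4 in pupae, hemocyte genes 2 higher of 3, with Pxn at 2.00, and activity-regulated genes 1 lower of 3, which was Hr38. The activity-regulated gene Jra was called higher with age in gamergates and lost that call without gamergate replicate 1 (0.52, adjusted p = 0.0729), among other omissions. Of 546 long noncoding RNAs, 66 were higher and 158 lower in pupae, against 2970 and 2476 of 9310 protein-coding genes.

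The ribosomal protein and oxidative phosphorylation lists passed camera as lower in duelers and in day 120 gamergates than in workers, with no member called singly and no call kept with an estimated correlation (adjusted p = 0.923 at day 10, 0.776 and 0.631 at day 120). These genes are short, so a trend of library values on gene length could produce such a difference. After removal of that trend, ribosomal proteins kept 0.853 of their difference at day 10 and 0.544 at day 120, and oxidative phosphorylation kept 0.759 and 0.783, so length may account for part of the ribosomal difference at day 120. Spread between libraries may account for the ribosomal difference at days 10 and 120 (exact permutation p = 0.159 and 0.321) and for oxidative phosphorylation at day 10 (exact permutation p = 0.429). It is less likely for oxidative phosphorylation at day 120 (exact permutation p = 0.0333), but is not excluded after adjustment over lists (adjusted p = 0.143).

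The level of apd-3l may follow adhering eye or cuticle tissue. Over 18 libraries of days 10 and 20, centred on their groups, apd-3l correlated with the retina list at r = 0.713 (permutation p = 0.0058, adjusted p = 0.0232 over 8 relations), or 0.634 without the 2 farthest libraries, and at 0.765 and 0.683 within the runs. It correlated with other cuticle genes at 0.828 (permutation adjusted p = 0.0016), while for muscle r was 0.367 (permutation p = 0.242), which leaves that tissue undecided, and for sequencing depth -0.149 (permutation p = 0.726). The cuticle maturation of young adults could be another cause and was not tested.

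The count of genes called between castes at day 120 moved with the run term and with 1 library. A difference between runs would likely shrink within 1 run. Over 41 genes called only without the run term, the batch 4 difference was by the median 0.84 of that without it. The quartiles of that ratio were 0.786 and 0.948, so most of these differences were somewhat smaller within batch 4. Batch 4 held 5 of the 6 gamergates and 5 of the 9 hunting workers, so it largely sets both values. A strong shrinkage could hardly show, and the ratio does not settle whether runs played a part. Without gamergate replicate 1 the called genes kept a median of 0.977 of their size. That fit returns the batch 4 difference, so it is not separate evidence. A large drop was unlikely from the start, since batch 4 holds most of the libraries. The differences were thus present in batch 4 without that library. The loss of calls may come from precision, since gamergate replicate 1 is the only gamergate of batch 1.

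Regrouping the same libraries at random gave as many calls, counting the real grouping, in 14 of 100 splits for caste at day 10 (real 2, highest other 1263) and 17 of 100 at day 20 (real 1, highest other 1422). Chance is therefore not excluded for those counts, and splits with many calls point to a structure of the samples other than caste. For caste at day 120 it was 3 of 100 (real 6, highest other 26). Those day 120 splits were drawn across both runs, not within them, so their balance of runs differed from the real one. For age it was 2 of 100 in workers (real 2460, highest other 3305) and 1 of 100 in gamergates (real 2510, highest other 1274), and for pupae 1 of 35 (real 5726, highest other 3763). For the interactions the real count was 0, which all 100 splits reach by construction, so the splits say nothing about chance there. Their highest other counts were 2638, 51 and 443.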
